A study of Mus musculus with 18 samples.

How the data were processed

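RNA had been extracted with Trizol from medulloblastomas of mice, copied into biotin-labelled cDNA and hybridized to Affymetrix mouse Gene ST 1.0 arrays, with 1 array per labelled tumour and 18 arrays in 5 groups. The groups were NG-Ptch (n = 4), GFD-Ptch (n = 2), GFI-Ptch (n = 4), NG-Smo;Atoh1-CreER (n = 4) and GFD-Smo;GFAP-cre (n = 4), and the last pair are called NG-Smo and GFD-Smo from here on. NG, GFD and GFI are subtype names that the labels leave unexplained. In the Smo tumours the subtype and the Cre driver were the same split of the arrays, so the effect of either could not be separated from the other. GFI-Ptch replicate 4 was described in its labels as a tumour that had progressed from another one and was grown in an NSG female host, and it is called the transplanted tumour.

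The deposited values were on the log2 scale, for 35556 probe sets and 18 arrays, with no value missing and a range of 4.219 to 14.32. The base was read from the values, since a 16-bit scanner intensity has a natural log of at most 11.09. The authors' processing notes named Partek 6.6 without its settings. The arrays had medians of 7.736 to 7.868 and lower quartiles of 6.21 to 6.382, and whether and how they had been scaled to each other was not stated. Background correction and the summary of probes were not stated either. For arrays, precision is limited by their number, and no depth applies.

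Of the probe sets, 23410 were in the probe table, 21789 of them with 1 gene symbol and 1621 with several, while 12146 had none there. Probe sets with exactly 1 symbol were kept, and where a gene had several (999 genes) the probe set with the highest mean over all arrays stood for it, which left 19938 genes. Of the probe sets, 21698 had an Entrez identifier in the RefSeq gene table, and 0 symbols differed between the tables. No filter on dim genes was applied and no value was changed. The files gave no coordinates.

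All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean for each of the 5 groups and 1 shared estimate of the spread per gene (13 residual and 2.448 prior degrees of freedom). Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over the 19938 genes, and a gene was called at an adjusted p under 0.05. The 8 contrasts were GFD minus NG, GFI minus NG and GFI minus GFD in Ptch tumours, GFD minus NG in Smo tumours, Smo minus Ptch in NG and in GFD tumours, the average of GFD minus NG over both models, and the difference of GFD minus NG between the models. Changes are log2 values with their standard error (SE), and group levels are means with the standard deviation (SD). Tables and plots were drawn with Python 3.11.15. The p-values measure only the spread between these samples, since the labels do not say whether replicates came from separate animals.

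The 26 gene lists held 366 genes, 342 of them measured (337 different ones). They covered the Shh pathway, granule neuron progenitors, differentiated neurons, neural stem cells, astrocytes, oligodendrocyte progenitors, oligodendrocytes, microglia and macrophages, lymphocytes, endothelium, fibroblasts and pericytes, erythrocytes, Purkinje cells and interneurons, choroid plexus, S phase, mitosis, the interferon response, MHC class II, the Notch pathway, mesenchymal genes, FGF and EGF signalling, PI3K and IGF signalling, the Wnt pathway, Polycomb and DNA methylation, p53 targets, and hypoxia and glycolysis. Of the 10 erythrocyte genes 3 were measured. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Another test, fry, asked whether a list's genes shifted together up or down, not whether they changed at all, without setting them against other genes. Each was adjusted over the 26 lists of a contrast. A list's value is the median log2 change of its members. Members were counted as called over all genes and as adjusted over the list alone.

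Genes were named by a rule. It took the 10 largest increases and the 10 largest decreases with an adjusted p under 0.05, a log2 change of at least 1 in size and no overlap between the arrays of the groups compared (6 and 6 for the Smo minus Ptch contrasts and the difference between models). For the average the groups had to be apart within either model, and for the difference between models no such condition was set. A fixed list of 11 sex-linked genes (which lacked the Y-linked Uba1y), predicted or unnamed loci, olfactory and vomeronasal receptors and immunoglobulin and T-cell receptor segments were left out of the rule. Ptch1, Smo, Gli1, Hhip, Mycn, Atoh1, Sox2, Olig2, Gfap, Egfr and Fgfr1 could always be named, as could up to 4 members of each list with the largest change. Groups, contrasts, lists, the rule and the alternatives below were chosen before the data were examined, except where stated.

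The alternatives were quantile normalization over the deposited values, median centring, a filter that kept genes with a group mean above the median of all values (7.803), the mean over a gene's probe sets, a fit of the compared groups only, a trended and robust prior, array weights, the gender label as a covariate, a replicate block, and leaving out each array in turn. Leaving out an array of a group outside a contrast changes only the shared spread, so the differences in that contrast stay as they were. The gender label entered as 3 levels, M, F and ND. Because 3 of the 4 NG-Ptch arrays were ND and both GFD-Ptch arrays M, that term overlaps with GFD minus NG in Ptch tumours. The label also went against the Y-linked genes in 3 of the 13 arrays labelled M or F, so it does not adjust for sex as measured on the arrays. A covariate for the level of Y-linked genes, a fit without the transplanted tumour and NG-Ptch replicate 4 together, and the lists and named genes without the transplanted tumour were added after the data were seen. The procedure was tested on simulated data, in 20 runs with 200 changed genes of 19938. For GFD minus NG in Ptch tumours 89.6% of genes changed by 1 log2 unit and 97.8% of genes changed by 2 were recovered, with 9.6 false calls per run. For GFI minus NG in Ptch tumours these were 93.2%, 98.8% and 11.1, and for GFD minus NG in Smo tumours 93.4%, 99.0% and 10.9. A list shifted by 0.6 was called in 100% of runs in each. The simulated genes were drawn independently, each with its own residual SD for all groups. The runs therefore do not show recovery or false calls where genes vary together, groups differ in spread or an array lies apart.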

Results

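Gene expression was measured in 18 mouse medulloblastomas, tumours of the cerebellum, of 3 subtypes named NG, GFD and GFI. The Ptch tumours comprised NG-Ptch (n = 4), GFD-Ptch (n = 2) and GFI-Ptch (n = 4), and the Smo tumours comprised NG-Smo;Atoh1-CreER (n = 4) and GFD-Smo;GFAP-cre (n = 4), written NG-Smo and GFD-Smo below. Ptch1 is the receptor that holds back Hedgehog signalling and Smo is the transducer it restrains. Across all genes, replicates correlated at 0.993 to 0.996 in NG-Ptch, 0.993 in GFD-Ptch, 0.970 to 0.992 in GFI-Ptch, 0.981 to 0.989 in NG-Smo and 0.995 to 0.998 in GFD-Smo. The first principal component held 31.2% of the variance and the second 16.2%, on which GFI-Ptch replicate 4, the transplanted tumour, scored -50.8. NG-Smo replicate 4 lay apart from its group as well. It scored -8.4 on the first and 13.9 on the second, against 3.3 to 10.2 and -14.1 to -3 in the other NG-Smo arrays. Its mean correlation was 0.9846 within its group and 0.9844 with other groups. Of 13 arrays with a male or female gender label, the Y-linked genes Eif2s3y, Kdm5d and Uty matched the label in 10 and went against it in 3, which were GFD-Smo replicates 2 and 3 and the transplanted tumour. Both GFD-Ptch arrays had Y-linked transcripts and no NG-Ptch array had them. At the level of Ptch1 (probe set 10410039) the groups read 11.56 ± 0.40 in NG-Ptch, 11.41 ± 0.21 in GFD-Ptch, 11.31 ± 0.51 in GFI-Ptch, 12.53 ± 0.24 in NG-Smo and 12.71 ± 0.13 in GFD-Smo (mean ± SD, n as above). Smo (10536917) lay between 11.31 ± 0.10 in GFD-Smo and 11.63 ± 0.06 in GFD-Ptch. Both genes are named in the group labels, so their differences between Ptch and Smo tumours cannot be separated from the genotype. Whether the Ptch1 probe set lies within an altered part of the gene is not known, so its level does not check the labels.

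**Figure D1:**
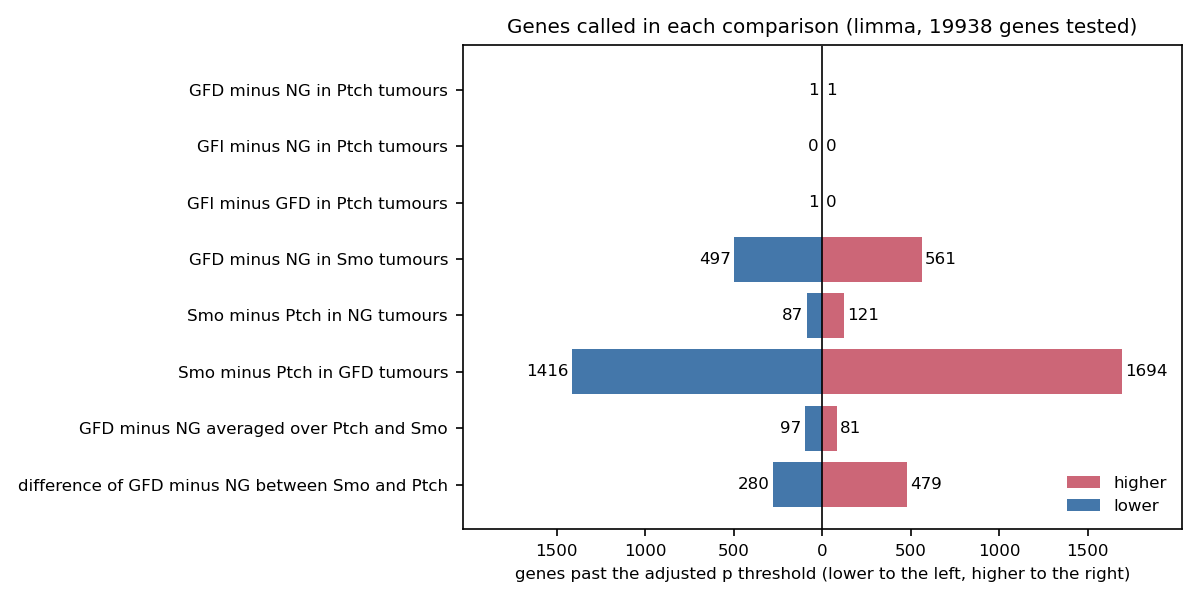
Number of genes past the adjusted p threshold in each of the 8 comparisons (limma, 19938 genes), with lower genes to the left and higher genes to the right on 1 linear axis. Smo minus Ptch in GFD tumours had 1694 higher and 1416 lower genes, and GFI minus NG in Ptch tumours had 0 of either.

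The first comparison asked how GFD and NG tumours of Ptch mice differed. The astrocyte and oligodendrocyte progenitor lists were lower in GFD-Ptch, while the oligodendrocyte list (-0.07, adjusted p = 0.120) was not called. These list calls are from camera at the preset correlation, and by fry 0 of the 26 lists passed in this comparison. The members named here were adjusted over their list alone and did not pass over all genes. The astrocyte list fell by a median of 0.67 with all 14 members below 0 (adjusted p = 1.06e-06, and adjusted p = 0.352 with an estimated correlation), and 4 members were lower when adjusted over the list alone. Among these 4 was Aldoc (10379153), a glycolytic enzyme of astrocytes, at 8.73 ± 0.06 in GFD-Ptch and 11.13 ± 0.56 in NG-Ptch (SD, n = 2 and n = 4). The water channel Aqp4 (10457614) was another, with a change of -1.83. The oligodendrocyte progenitor list fell by 0.77 in all 9 members (adjusted p = 2.49e-05, and adjusted p = 0.352 with an estimated correlation). Adjusted over the list alone 5 were lower, including Ptprz1 at -2.18, Lhfpl3 at -1.99 and the lineage factor Olig1 at -1.34. The neural stem cell list fell by 0.24 (adjusted p = 0.0173, and adjusted p = 0.352 with an estimated correlation). Sox2 (-1.67), Fabp7 (-1.39) and Slc1a3 (-1.23) were lower and Fut4 (0.22) higher when adjusted over the list alone.

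In the same comparison the microglia and macrophage list fell by 0.27 in 17 of 18 members (adjusted p = 2.49e-05, and adjusted p = 0.386 with an estimated correlation). C1qa, at -0.90, and Tyrobp, at -0.83, were lower when adjusted over the list alone. The hypoxia and glycolysis list rose by 0.36 in 11 of 12 members (adjusted p = 0.00334, and adjusted p = 0.352 with an estimated correlation). Bnip3 (0.89), the vasoactive peptide gene Adm (0.79) and Car9 (0.29) were higher when adjusted over the list alone. Also called were the FGF and EGF list (-0.28, adjusted p = 0.000782), the mesenchymal list (-0.18, 0.0364), the fibroblast and pericyte list (0.35, 0.0195), the lymphocyte list (0.14, 0.0173) and the endothelium list (0.33, 0.0377). With an estimated correlation their adjusted p was 0.352 for the first 3, 0.551 for lymphocytes and 0.633 for endothelium. Without GFD-Ptch replicate 1 the adjusted p was 0.25 for endothelium, 0.239 for fibroblasts and 0.149 for the mesenchymal list. The last of these also missed the threshold without NG-Smo replicate 4 (0.0549) or NG-Ptch replicate 5 (0.0712). Endothelium did so without NG-Ptch replicate 1 (0.0849), NG-Ptch replicate 5 (0.108) or NG-Smo replicate 4 (0.0579). With the gender label in the model the astrocyte list stood at -0.27 (adjusted p = 0.037), the oligodendrocyte progenitor list at -0.04 (adjusted p = 0.642), the stem cell list at 0.05 (0.883), the FGF and EGF list at -0.06 (0.494) and the hypoxia list at 0.29 (0.197). The mesenchymal list stood at 0.00 (0.597) and the lymphocyte list at 0.12 (0.0688) in that fit, and Zdhhc2, named below, at -1.25 (0.201). With the Y-linked level instead, a fit chosen after the data were seen, calls ended for the stem cell (-0.17, 0.122), FGF and EGF (-0.21, 0.0588), mesenchymal (-0.10, 0.209), fibroblast (0.23, 0.242), lymphocyte (0.17, 0.0519) and endothelium (0.19, 0.635) lists and for Zdhhc2 (-1.35, 0.133). The astrocyte list stood at -0.63 and the oligodendrocyte progenitor list at -0.95 there. Quantile normalization took the lymphocyte list to 0.07 (0.141) and ended its call. The lymphocyte score lay between 6.23 and 6.5 in all 18 arrays, near their lower quartiles of 6.21 to 6.382. Its shifts in this and the other contrasts therefore cannot be separated from background.

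Over all genes, 2 were called between GFD-Ptch and NG-Ptch, and 3375 had an unadjusted p under 0.05, where chance gives 997. Vopp1 (10545014) rose by 0.69 (SE 0.080, adjusted p = 0.00588) and was chosen after its values were seen. The palmitoyltransferase gene Zdhhc2 (10571399) fell by 1.58 (SE 0.218, adjusted p = 0.0232). The Hedgehog target Hhip (10579894) read 8.95 ± 0.29 against 10.14 ± 0.43 (SD, n = 2 and n = 4; change -1.19, adjusted p = 0.163). Gli1 differed by -0.28 and Ptch1 by -0.14, and none of the 3 was called. The count was 1 without NG-Ptch replicate 1 or 2 or GFD-Smo replicate 1 or 2, 4 without NG-Ptch replicate 4, 5 without GFI-Ptch replicate 3 or NG-Smo replicate 2, 6 without GFI-Ptch replicate 2, and 10 without NG-Smo replicate 1. It was 24 without GFI-Ptch replicate 1, 55 without GFD-Ptch replicate 1, 69 without NG-Smo replicate 4 and 144 without the transplanted tumour. Zdhhc2 missed the threshold without NG-Ptch replicate 1 (adjusted p = 0.0905), 2 (0.111) or 5 (0.0576), GFD-Ptch replicate 2 (0.312) or GFD-Smo replicate 1 (0.0508) or 2 (0.0515).

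Without the transplanted tumour 62 genes were higher and 82 lower in GFD-Ptch than in NG-Ptch. Leaving out each array in turn was planned, but the named genes and lists of this fit were added after the data were seen. That fit changes the shared spread and not the differences between these 2 groups. Hhip was then called (adjusted p = 0.0359). The genes lower in GFD-Ptch included Scrg1 at -2.45 (adjusted p = 0.00877), the gap junction gene Gjc3 at -2.46, Ptprz1 at -2.18, Lhfpl3 at -1.99, Cspg5 at -1.93 and Aqp4 at -1.83 (adjusted p = 0.0218). The higher ones included the oxygen sensor Egln3 at 1.63 (adjusted p = 0.0207), Prickle2 at 1.23 (0.0148), Acta2 at 1.21 and Uba1y, a Y-linked gene, at 2.84. The astrocyte, oligodendrocyte progenitor, stem cell and hypoxia lists then each had an adjusted p of 0.251 with an estimated correlation.

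**Figure D2:**
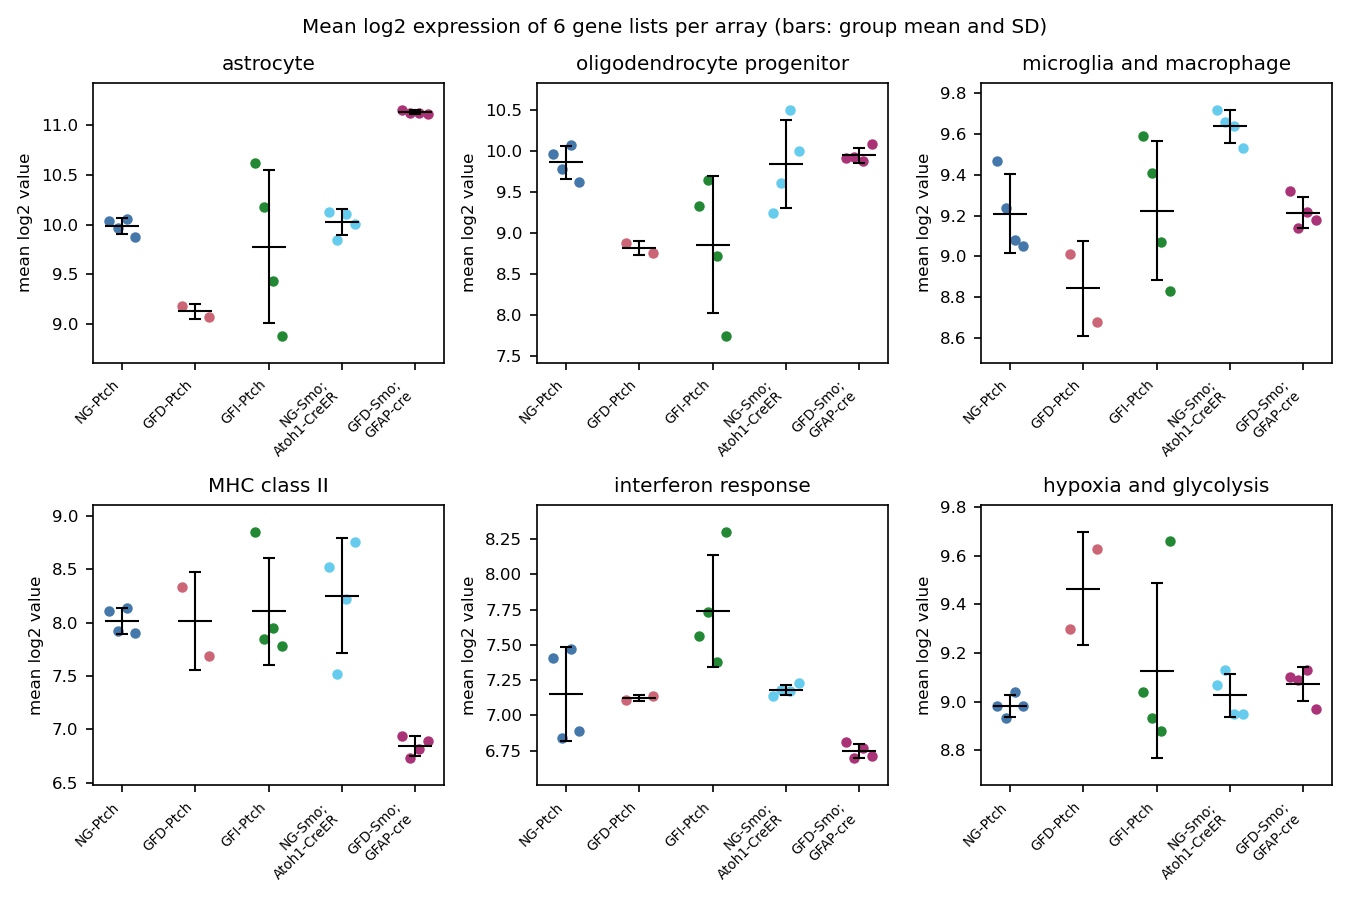
Mean log2 value of 6 gene lists per array (points), with the group mean and SD as bars, for the 5 groups. Astrocyte values were 9.12 in GFD-Ptch and 11.13 in GFD-Smo, with NG-Ptch at 9.99 and NG-Smo at 10.03.

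GFI and NG tumours of Ptch mice were compared next (n = 4 each). The interferon response list was higher in GFI-Ptch by camera at the preset correlation, while by fry 0 of the 26 lists passed in this comparison. All 14 interferon genes lay above 0 and the list rose by 0.54 (adjusted p = 5.10e-10, and adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone 10 were higher, such as the antiviral genes Ifit3, at 9.04 ± 0.57 in GFI-Ptch and 7.94 ± 1.01 in NG-Ptch (SD, n = 4 each), and Ifit1 (1.18), and Usp18 (1.17). The oligodendrocyte progenitor list fell by 1.02 in all 9 members (adjusted p = 5.10e-10, and adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone 7 were lower, including Olig1, at 8.49 ± 1.11 against 9.88 ± 0.13, and the growth factor receptor Pdgfra (-1.02). The differentiated neuron list fell by 0.34 in 17 of 19 members (adjusted p = 9.21e-08, and adjusted p = 0.174 with an estimated correlation). The neurofilament gene Nefl, at 7.02 ± 0.16 against 8.74 ± 0.30, Fat2 (-1.02), Nefm (-0.59) and Cbln1 (-0.58) were lower when adjusted over the list alone.

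Smaller shifts in GFI-Ptch were found in the granule neuron progenitor list (-0.06, adjusted p = 0.00659), where Tlx3 (-0.74), Cntn2 (-0.59) and Neurod1 (-0.48) were lower when adjusted over the list alone. The neural stem cell (-0.22, 0.00442), Shh pathway (-0.13, 0.0242) and fibroblast and pericyte lists (0.24, 0.0237) shifted too. With an estimated correlation the adjusted p was 0.174 for progenitors, 0.24 for stem cells and fibroblasts and 0.812 for the Shh pathway. These 4 lists lost their calls without the transplanted tumour. Stem cells then stood at -0.09 (adjusted p = 0.109) and the Shh pathway at -0.02 (0.668), both much smaller, while progenitors stood at -0.05 (0.0999) and fibroblasts at 0.21 (0.245), about as before. In that tumour genes of developing muscle lay a median of 2.80 above the other GFI-Ptch arrays, among them the embryonic myosin Myh3 (4.78). The Shh list also lost its call without NG-Ptch replicate 4 (0.180) and stood at 0.01 with the gender label in the model, where stem cells (-0.08, 0.606) and progenitors (-0.04, 0.257) lost theirs too. The fibroblast list lost it without NG-Ptch replicate 1 (0.0656) or 5 (0.0633) or GFI-Ptch replicate 3 (0.0527), and stood at 0.20 (0.107) with the Y-linked level in the model. The interferon, oligodendrocyte progenitor and neuron lists stayed past the threshold without the transplanted tumour, at 0.36, -0.59 and -0.24, each with an adjusted p of 0.553 with an estimated correlation.

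No gene was called between GFI-Ptch and NG-Ptch by limma (0 of 19938), and 1701 had an unadjusted p under 0.05, where chance gives 997. With some other settings, array weights and median centring among them, genes were called, as counted below. Zdhhc2, the gene with the lowest adjusted p (0.0579, chosen after its values were seen), differed by -1.13. The count was 5 without the transplanted tumour, all lower and chosen after their values were seen. These were Adamtsl3, Ttyh2 (-0.71), Mgat5b (-0.65), Rac3 (-0.60) and the ion channel Trpv2 (-0.25). It was 8 without GFI-Ptch replicate 2, 4 without GFD-Ptch replicate 1 or 2 and 1 without NG-Smo replicate 2. The number of lists called was 7, and 3 without the transplanted tumour.

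Comparing GFI-Ptch (n = 4) with GFD-Ptch (n = 2), the astrocyte and microglia lists were higher in GFI-Ptch by camera at the preset correlation. By fry 0 of the 26 lists passed in this comparison. The astrocyte list rose by 0.55 in all 14 members (adjusted p = 4.25e-06, and adjusted p = 0.333 with an estimated correlation), with Clu at 1.36 and Sparcl1 at 0.99 adjusted over the list alone. The microglia and macrophage list rose by 0.43 in all 18 members (adjusted p = 8.01e-07, and adjusted p = 0.333 with an estimated correlation), with the complement gene C1qa at 0.91 adjusted over the list alone. The interferon list rose by 0.58 (adjusted p = 3.55e-07), with Ifit3 at 1.79, and the FGF and EGF list by 0.16 (0.006). The hypoxia and glycolysis list fell by 0.30 (0.00213), with Bnip3 at 9.47 ± 0.64 in GFI-Ptch and 10.48 ± 0.44 in GFD-Ptch (SD). These 3 had an adjusted p of 0.333 with an estimated correlation. The differentiated neuron list fell by 0.38 (adjusted p = 3.31e-05, and adjusted p = 0.333 with an estimated correlation), with Fat2 at -1.38. The endothelium list fell by 0.45 (adjusted p = 0.0015, and adjusted p = 0.423 with an estimated correlation), with Cdh5, the cadherin of endothelial junctions, at -0.83 and the receptor Kdr at -0.57.

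Vopp1 was the 1 gene called in GFI-Ptch against GFD-Ptch, at -0.69 (adjusted p = 0.00562), and 1952 genes had an unadjusted p under 0.05. The count was 47 without the transplanted tumour, 15 without GFI-Ptch replicate 3 and 2 without GFI-Ptch replicate 2. It was 14 without GFD-Ptch replicate 1, 3 without GFD-Ptch replicate 2 and 6 without NG-Smo replicate 2. Without the transplanted tumour 11 lists were called, against 7. Genes higher in GFI-Ptch then included the glutamate receptor Gria1 (2.11), Plpp3 (1.84) and the glutamate transporter Slc1a3 (1.47), while Egln3 (-1.66) and Bnip3 (-1.32) were lower. The astrocyte list then stood at 0.79 (adjusted p = 3.95e-14, and adjusted p = 0.080 with an estimated correlation) and the hypoxia list at -0.43 (2.35e-08, and adjusted p = 0.0309 with an estimated correlation). Without GFD-Ptch replicate 1 the neuron (adjusted p = 0.0654) and endothelium (0.0786) lists missed the threshold. Without GFD-Ptch replicate 2 these were the hypoxia (0.0987) and FGF and EGF (0.0780) lists, and without GFI-Ptch replicate 1 the FGF and EGF list (0.0784), which with the gender label stood at 0.08 (0.168). With the Y-linked level the FGF and EGF (0.14, 0.0995) and endothelium (-0.34, 0.147) lists were not called.

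The Smo tumours were compared as GFD-Smo with NG-Smo (n = 4 each), where subtype and Cre driver went together. Astrocyte genes were higher in GFD-Smo. Of 14 members 8 were called over all genes and 10 adjusted over the list alone. The list rose by 1.08 (adjusted p = 1.21e-10, and adjusted p = 0.162 with an estimated correlation), and its score was 11.13 ± 0.020 in GFD-Smo against 10.03 ± 0.13 in NG-Smo (SD). The gap junction gene Gja1 (10363173) was at 11.36 ± 0.08 against 9.05 ± 0.59 (change 2.32, SE 0.33, adjusted p = 0.000646). Gjb6 rose by 2.08, Aqp4 by 1.89, Aldh1l1 by 1.52, Fgfr3 by 1.27 and the intermediate filament Gfap by 1.11 (adjusted p = 0.0188). Genes of antigen presentation were lower in GFD-Smo. The MHC class II list fell by 1.12 in all 6 members (adjusted p = 3.56e-06, and adjusted p = 0.162 with an estimated correlation). H2-Aa (10450154) was at 5.85 ± 0.14 against 9.42 ± 0.75 (change -3.57, SE 0.41, adjusted p = 0.000109). The invariant chain gene Cd74 at -1.94 and H2-Ab1 at -1.34 were called too, and 5 members were lower when adjusted over the list alone.

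Myeloid genes were lower in GFD-Smo as well. The microglia and macrophage list fell by 0.33 in 14 of 18 members (adjusted p = 5.30e-06, and adjusted p = 0.240 with an estimated correlation). The lysozyme gene Lyz2 (10372648) at -1.79, Ptprc at -1.10, Ctss at -1.02 and Aif1 at -0.35 were called over all genes, and 9 members were lower when adjusted over the list alone. The interferon list fell by 0.44 in all 14 members (adjusted p = 5.30e-06, and adjusted p = 0.208 with an estimated correlation), with the chemokine Cxcl10 at -1.26. Among the largest decreases were the iron-sequestering protein gene Lcn2 (10481627), which fell by 4.16 (6.73 ± 0.38 against 10.89 ± 0.89, adjusted p = 0.000312), and Wfdc17 (-3.21). On these arrays Xist read 6.6 to 7.21 where Y-linked transcripts were present, and Kdm5d 5.78 in NG-Ptch, where they were absent. The low levels of Lcn2 and H2-Aa therefore cannot be separated from background, and their changes are lower limits if they lie there. The other decreases were the transferrin gene Trf (-1.96), Atp6v0d2 (-1.86), Gpnmb (-1.85), the ceruloplasmin gene Cp (-1.83), BC040756 (-1.96) and Adamdec1 (-2.01). The p53 target list fell by 0.44 in all 8 members (adjusted p = 3.48e-05, and adjusted p = 0.162 with an estimated correlation). Phlda3 at -1.30, Sesn2 at -0.74 and Zmat3 at -0.52 were called over all genes, and 6 members were lower when adjusted over the list alone.

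The largest increase in GFD-Smo was that of Prm1 (10437684), a protamine gene of sperm chromatin, which rose by 4.26 (11.68 ± 0.09 against 7.42 ± 0.22, SE 0.41, adjusted p = 2.56e-05). Zdbf2 (3.40, SE 0.73, adjusted p = 0.0119) and Grb10 (2.70, SE 0.37, adjusted p = 0.000418), the latter an adaptor that dampens growth factor receptors, were also higher. So were the telomerase RNA gene Terc (2.43), Gpr50 (3.59), Mtx2 (2.97), Prex2 (2.41), the glutamate receptor Grm3 (2.31) and the GABA receptor subunit Gabrg1 (2.19). In the Hedgehog pathway Hhip rose by 1.14 (SE 0.28, adjusted p = 0.0228) and Gli3 by 1.83 while Ccnd2 fell by 0.61. The list as a whole stood at 0.09 (adjusted p = 0.183). Ptch1 (0.19), Smo (-0.27), Gli1 (0.36) and Sox2 (0.87) were not called, and Gli1 was without the transplanted tumour (adjusted p = 0.0272). In the list of Polycomb and DNA methylation genes, which stood at -0.14 (adjusted p = 0.513), the RNA-binding protein gene Igf2bp1 rose by 1.33 and Tet2 by 0.43. Bmi1 fell by 0.44, Dnmt1 by 0.29 and Ezh2 by 0.27.

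Notch pathway genes rose by 0.41 in GFD-Smo (adjusted p = 5.48e-06, and adjusted p = 0.162 with an estimated correlation). Nrarp at 0.84 and Notch3 at 0.53 were called, and 8 members were higher when adjusted over the list alone. The fibroblast and pericyte list rose by 0.46 (adjusted p = 8.17e-05, and adjusted p = 0.162 with an estimated correlation), with the pericyte receptor Pdgfrb at 0.74 among 5 called members. The endothelium (0.39, 2.19e-05), neural stem cell (0.34, 0.0023), FGF and EGF (0.17, 0.000461) and Purkinje and interneuron lists (0.74, 2.68e-05) rose too, each with an adjusted p of 0.208 with an estimated correlation. In the last list no member was called over all genes and 5 were adjusted over the list alone, with Calb1 at 2.29, and its score ran from 7.84 to 9.51 among the GFD-Smo arrays. The lymphocyte (-0.07, 0.0367), choroid plexus (0.44, 0.0368) and S phase (-0.11, 0.0311) lists passed narrowly, with adjusted p of 0.622, 0.622 and 0.641 with an estimated correlation. Choroid plexus stood at -0.01 without GFD-Smo replicate 2, whose score was 9.68 (adjusted p = 0.534). It also missed the threshold without NG-Smo replicate 2 (0.1), 3 (0.0806) or 4 (0.0802) or the transplanted tumour (0.0590). The S phase list missed it without NG-Smo replicate 1 (0.0589), 2 (0.459) or 3 (0.137) or GFD-Smo replicate 4 (0.0571). The lymphocyte list did so without NG-Smo replicate 4 (0.249) or GFD-Smo replicate 4 (0.130), and S phase with the Y-linked level in the model (-0.09, 0.0736).

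In total 561 genes were higher and 497 lower in GFD-Smo than in NG-Smo, of which 141 and 63 changed at least 2-fold. The count of 1058 was 672, 643 and 666 without GFD-Smo replicates 1, 2 and 3. Hhip missed the threshold without NG-Smo replicate 1 (adjusted p = 0.0582) or 4 (0.0630) or without GFD-Smo replicate 1 (0.0530), 2 (0.0639), 3 (0.0519) or 4 (0.0636). Gfap missed it without NG-Smo replicate 1 (0.0529) or GFD-Smo replicate 1 (0.0668) or 4 (0.0560), and Adamdec1 without NG-Smo replicate 1 (0.0554).

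**Figure D3:**
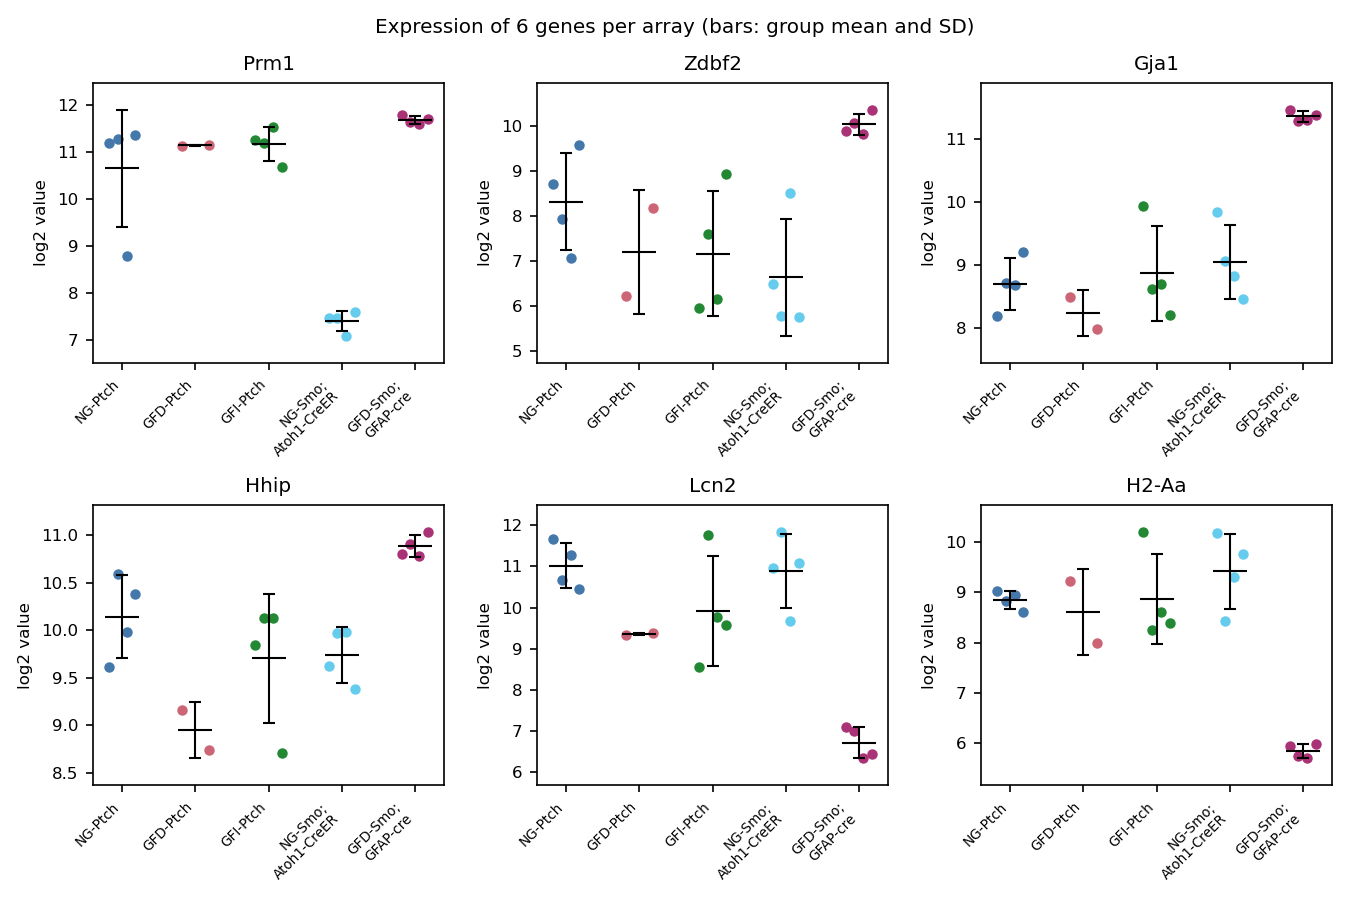
Log2 value of 6 genes per array (points), with the group mean and SD as bars, for the 5 groups. Prm1 was at 7.42 in NG-Smo and 11.68 in GFD-Smo, and H2-Aa at 9.42 and 5.85.

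NG tumours of the 2 models were compared as NG-Smo minus NG-Ptch (n = 4 each). Myeloid genes were higher in NG-Smo. The microglia and macrophage list rose by 0.39 in all 18 members (adjusted p = 3.93e-10, and adjusted p = 0.409 with an estimated correlation). The fractalkine receptor Cx3cr1 at 0.91, Ptprc at 0.56 and Aif1 at 0.48 were called over all genes, and 9 members were higher when adjusted over the list alone. The granule neuron progenitor list fell by 0.18 in 13 of 16 members (adjusted p = 0.000679, adjusted p = 0.0565 with an estimated correlation and 0.0125 by fry). It was the only list that passed by fry in this contrast. The transcription factors Pax6 (-1.08), Tlx3 (-0.61) and Nhlh2 (-0.40) were lower when adjusted over the list alone. Among single genes, the protease gene Ctse (10349648) was at 8.25 ± 0.38 against 6.65 ± 0.09 (change 1.60, SE 0.14, adjusted p = 6.7e-05), and Dmrtb1 at 8.84 ± 0.44 against 7.36 ± 0.09 (adjusted p = 0.000237). BC040756 (1.98), Npl (1.95), the protocadherin Pcdhb6 (1.72) and the laminin gene Lama5 (1.47) were higher too. The interferon-inducible Ifi203 (10360391; -2.56, SE 0.28, adjusted p = 0.000572), Prm1 (-3.24, SE 0.41, adjusted p = 0.00164), Rgs13 (-2.99), Foxd1 (-1.89), the receptor gene Ret (-1.61) and AI593442 (-1.28) were lower.

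Of the other lists in NG tumours, the Shh pathway fell by 0.31 (adjusted p = 0.000679). The pathway inhibitor Sufu was called over all genes at -0.59, with 2 members higher and 7 lower when adjusted over the list alone. Differentiated neurons fell by 0.17 (0.00581), while oligodendrocytes (0.42 in all 11 members, 0.00142), endothelium (0.26, 0.00391), fibroblasts and pericytes (0.12, 0.0313) and p53 targets (0.29, 0.0187) rose. With an estimated correlation the adjusted p was 0.592 for Shh and fibroblasts, 0.655 for p53 targets and 0.661 for the others. Without NG-Smo replicate 3 the neuron (0.147), endothelium (0.275), fibroblast (0.275) and p53 (0.275) lists lost their calls. Without NG-Ptch replicate 1 the same happened to the neuron (0.050), endothelium (0.0595), fibroblast (0.0981) and p53 (0.0981) lists. The number of lists called was 4 and 5 in these fits, against 8. The oligodendrocyte list stood at 0.14 (0.235) without NG-Smo replicate 4 and at 0.21 (0.147) with array weights, and was called in neither. The call of fibroblasts was lost without NG-Ptch replicate 5 (0.0602) and that of p53 targets without NG-Ptch replicate 4 (0.0526). Ptch1 differed by 0.97 (adjusted p = 0.0544) and was called at 1.16 without NG-Ptch replicate 4 (0.0298) and at 0.97 without GFI-Ptch replicate 3 (0.0428) or the transplanted tumour (0.0130).

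Together 208 genes were called in NG tumours, 121 higher and 87 lower in NG-Smo, with 22 and 12 changed at least 2-fold. The count was 75, 86 and 84 without NG-Ptch replicates 2, 4 and 5, and 384 without the transplanted tumour or NG-Smo replicate 4. It was 127 and 95 without NG-Smo replicates 2 and 3, and 119, 122, 116 and 126 without GFD-Smo replicates 1, 2, 3 and 4. Lama5 missed the threshold when any of 15 of the 18 arrays was left out (adjusted p from 0.0526 to 0.145), all but GFI-Ptch replicates 1 and 4 and NG-Smo replicate 4. Rgs13 did so with any of 13, all but the GFI-Ptch arrays and NG-Smo replicate 4 (0.0504 to 0.123). Foxd1 missed it without any NG-Ptch array or NG-Smo replicate 1, 2 or 3 (0.0542 to 0.0852). Ret did so without NG-Ptch replicate 2, 4 or 5 or NG-Smo replicate 1 or 2 (0.0521 to 0.0824). Prm1 missed it when the compared groups alone were fitted (adjusted p = 0.0709), as did BC040756 (0.0535). Rgs13 (0.102) and Ret (0.0512) missed it with the gender label in the model. Lama5 (0.127), Ret (0.0622) and the endothelium (0.23, 0.175) and fibroblast (0.06, 0.230) lists missed it with the Y-linked level. NG-Ptch replicate 4 had a Prm1 level of 8.80 where the other 9 Ptch arrays had 10.69 to 11.54.

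GFD tumours of the 2 models differed in more genes, with GFD-Smo (n = 4) against GFD-Ptch (n = 2). Glial genes were higher in GFD-Smo. All 14 astrocyte genes lay above 0, with 11 called and 13 adjusted over the list alone. The list rose by 1.99 (adjusted p = 6.51e-12, and adjusted p = 0.311 with an estimated correlation). Aldoc was at 12.82 ± 0.13 against 8.73 ± 0.06 (change 4.09, SE 0.81, adjusted p = 0.0036), Scrg1 at 10.66 ± 0.15 against 6.80 ± 0.25, and Plpp3 at 11.63 ± 0.14 against 7.98 ± 0.52 (adjusted p = 2.2e-05). The oligodendrocyte progenitor list rose by 0.64 with Ptprz1 at 3.34 and Lhfpl3 at 2.15 among 4 called members (adjusted p = 0.00381, and adjusted p = 0.566 with an estimated correlation). The neural stem cell list rose by 0.46 with Sox2 at 2.46, Tnc at 2.31 and Slc1a3 at 2.20 among 5 (adjusted p = 0.00324, and adjusted p = 0.326 with an estimated correlation). Among signalling genes, the FGF and EGF list rose by 0.39 (adjusted p = 8.97e-06, and adjusted p = 0.311 with an estimated correlation). It had 8 called members, such as the receptors Fgfr2 (2.02) and Fgfr3 (1.63), and 11 adjusted over the list alone. The Notch list rose by 0.46 with 7 called, such as the ligand Jag1 at 1.76 (adjusted p = 0.000102, and adjusted p = 0.316 with an estimated correlation).

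Of the Hedgehog genes in GFD tumours, Hhip was at 10.88 ± 0.12 against 8.95 ± 0.29 (change 1.93, SE 0.34, adjusted p = 0.00146). Gli3 rose by 1.69, Ccnd2 fell by 1.07, and the list stood at -0.05 (adjusted p = 0.766). Ptch1 was higher by 1.30 (SE 0.28, adjusted p = 0.00549), which cannot be separated from the genotype of the Ptch tumours. Other large differences were Gpr50 (4.49), the lipid desaturase Scd1 (3.83) and Gjc3 (3.68) among the higher genes. Tecta (-3.51), Ifi203 (-3.12, SE 0.35, adjusted p = 5.5e-05), the Y-linked Uba1y (-2.83), H2-Aa (-2.76), Lcn2 (-2.63) and Minar1 (-2.51) were among the lower ones. The MHC class II list fell by 1.07 with 4 of 6 called (adjusted p = 0.0128, and adjusted p = 0.555 with an estimated correlation). The hypoxia list fell by 0.36 with Bnip3 at -0.93 (adjusted p = 0.044, and adjusted p = 0.555 with an estimated correlation). The microglia list rose by 0.34 with Csf1r, the receptor that maintains microglia, at 1.31 (adjusted p = 0.0053), and the oligodendrocyte list by 0.60 with Cnp at 2.85 (0.00918). The endothelium list rose by 0.26 (0.0255) and the Purkinje list by 0.93 with Car8 at 3.11 (0.00324), while the lymphocyte (-0.17, 0.0268) and interferon (-0.26, 0.0461) lists fell. With an estimated correlation the adjusted p was 0.555 for Purkinje, 0.628 for interferon and 0.566 for the other 4.

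There were 3110 called genes between the GFD groups, 1694 higher and 1416 lower in GFD-Smo, with 449 and 112 changed at least 2-fold. The count was 1714 and 997 without GFD-Ptch replicates 1 and 2. Without GFD-Ptch replicate 1 the calls of Uba1y (-1.11, adjusted p = 0.0596), Lcn2 (0.0743), Sox2 (0.0509), the MHC class II list (-0.70, 0.120) and the interferon list (0.0603) ended. Without replicate 2 those of Lcn2 (0.120), Sox2 (0.0565), Ptch1 (0.0907), Gfap (0.72 against 1.19, 0.340) and the microglia (0.17, 0.0902), interferon (0.0902) and hypoxia (-0.20, 0.168) lists ended. Gfap also missed the threshold without GFD-Smo replicate 1 (0.0501), endothelium without GFD-Smo replicate 2 (0.0536), and hypoxia without NG-Smo replicate 4 (0.0572) or GFD-Smo replicate 4 (0.0543). The interferon list missed it also without GFI-Ptch replicate 1 (0.0525), NG-Smo replicate 1 (0.0531), 3 (0.0519) or 4 (0.0572) or GFD-Smo replicate 2 (0.0674). With the gender label in the model Gfap stood at 0.73 (0.0963), the oligodendrocyte progenitor list at 0.17 (0.182) and the microglia list at 0.18 (0.0518), and none was called. The endothelium (0.20), interferon (-0.26, 0.170) and hypoxia (-0.34, 0.182) lists lost their calls there as well. With the Y-linked level the oligodendrocyte list stood at 0.13 (0.105) and Gfap at 0.95 (0.0826), neither called. With the filter on dim genes the oligodendrocyte (0.68, 0.0919), microglia (0.34, 0.0919) and endothelium (0.26, 0.175) lists were not called. Quantile normalization ended the calls of the lymphocyte (-0.09, 0.150), interferon (-0.18, 0.0796) and endothelium (0.31, 0.0552) lists.

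GFD minus NG was then averaged over both models, and such an average can come from 1 of them. Myeloid genes were lower in GFD, with the microglia list at -0.27 in Ptch and -0.33 in Smo tumours. The microglia and macrophage list fell by 0.28 in all 18 members (adjusted p = 2.35e-11, adjusted p = 0.266 with an estimated correlation and 0.0381 by fry). Lyz2 (-1.32, SE 0.20, adjusted p = 0.00679), Ctss (-0.83), C1qa (-0.80) and Ptprc (-0.67) were called, and 9 members were lower when adjusted over the list alone. The oxidase subunit gene Cybb (10603551) fell by 1.15 (SE 0.11, adjusted p = 0.000274). Its level was 9.64 in NG-Ptch, 9.08 in GFD-Ptch, 10.42 ± 0.12 in NG-Smo and 8.67 ± 0.24 in GFD-Smo. Lcn2 (-2.91, SE 0.43, adjusted p = 0.00612), Cp (-1.50), Atp6v0d2 (-1.50), Gpnmb (-1.48), the complement gene C4b (-1.32), the inflammatory caspase Casp4 (-1.24), Trf (-1.12) and the fungal receptor gene Clec7a (-1.11) were lower too, and Terc (1.66) was higher.

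Vascular and stromal lists rose in that average. The fibroblast and pericyte list rose by 0.41 (adjusted p = 9.74e-06, adjusted p = 0.071 with an estimated correlation and 0.00505 by fry). Pdgfrb at 0.57 and Col1a2 at 0.45 were among 4 called members, and 7 were higher when adjusted over the list alone. The endothelium list rose by 0.31 in all 12 members (adjusted p = 1.30e-06, adjusted p = 0.266 with an estimated correlation and 0.0381 by fry), with Kdr at 0.60 and Ramp2 at 0.50. The oligodendrocyte progenitor (-0.47, 0.000513), MHC class II (-0.60, 0.000208), interferon (-0.17, 0.000208), p53 (-0.11, 0.00462), S phase (-0.10, 0.0048) and mesenchymal (-0.07, 0.0187) lists fell, and the hypoxia (0.27, 0.0048) and erythrocyte (0.13, 0.0196) lists rose. With an estimated correlation the adjusted p of these 8 lay between 0.266 for the mesenchymal list and 0.579 for S phase. Several of these averages came from 1 model. In Ptch and Smo tumours MHC class II stood at 0.08 and -1.12, interferon at 0.02 and -0.44, p53 at 0.05 and -0.44, oligodendrocyte progenitors at -0.77 and -0.01 and hypoxia at 0.36 and 0.06, and these 5 also differed between the models. With the gender label in the model 5 of these lists lost their calls, oligodendrocyte progenitors at -0.02 (adjusted p = 0.665), mesenchymal at 0.00 (0.327), p53 at -0.04 (0.248), hypoxia at 0.17 (0.161) and S phase at -0.08 (0.0919). So did Terc (0.201), Cp (0.0544), Atp6v0d2 (0.116), Gpnmb (0.111), C4b (-0.91, 0.155) and Clec7a (0.0655). With the Y-linked level the same 6 genes (0.0551 to 0.0956) and the mesenchymal list (-0.02, 0.0598) were not called.

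The average gave 81 higher and 97 lower genes, of which 5 and 13 changed at least 2-fold. The count of 178 was 89 and 84 without NG-Ptch replicates 1 and 2, and 98 and 13 without GFD-Ptch replicates 1 and 2. It was 358 without the transplanted tumour, 281 without NG-Smo replicate 4, and 91, 88 and 95 without GFD-Smo replicates 1, 2 and 3. Cybb kept its call without any 1 array. Without GFD-Ptch replicate 2 Lcn2 (adjusted p = 0.0708), Lyz2 (0.0927), Casp4 (0.0927), Trf (0.0978), Cp (0.163), Terc (0.128), Atp6v0d2 (0.332), Gpnmb (0.238), C4b (0.249) and Clec7a (0.271) missed the threshold. So did the erythrocyte (0.0854), S phase (-0.03, 0.195), p53 (-0.04, 0.185) and hypoxia (0.18, 0.0763) lists. Without GFD-Ptch replicate 1, NG-Ptch replicate 1 or 2, or GFD-Smo replicate 2 or 3, Terc, Atp6v0d2, Gpnmb, C4b and Clec7a missed it as well, at 0.0548 or more. Each of these 5 also missed it without some of NG-Ptch replicates 4 and 5, GFI-Ptch replicate 2, NG-Smo replicates 1 to 3 and GFD-Smo replicates 1 and 4, at 0.0504 or more. The S phase list missed it without NG-Smo replicate 2 (0.0665). The mesenchymal list did so without GFD-Ptch replicate 1 (0.0707) or NG-Smo replicate 4 (0.0632).

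The difference of GFD minus NG between the models tested where Smo and Ptch tumours parted. Astrocyte genes parted most among the lists. The list differed by 2.07 with all 14 members above 0 and 10 called (adjusted p = 3.98e-13, adjusted p = 0.228 with an estimated correlation and 0.0205 by fry). Aqp4 differed by 3.72 (SE 0.55, adjusted p = 0.00213), as its level was 8.82 in GFD-Ptch and 10.65 in NG-Ptch against 12.32 in GFD-Smo and 10.43 in NG-Smo, and Gfap by 1.88 (SE 0.41, adjusted p = 0.0197). Hhip differed by 2.33 (SE 0.44, adjusted p = 0.00907). Mtx2 (4.89), Zdbf2 (4.51), Aldoc (4.39), Scd1 (3.90) and Prm1 (3.78, SE 0.65, adjusted p = 0.00588) were the other large positive differences. The negative ones were H2-Aa (-3.32), Uba1y (-2.98), Tbx15 (-2.97), BC040756 (-2.84, SE 0.48, adjusted p = 0.00518), Wfdc17 (-2.76) and Pcdhb2 (-2.40). Sox2 differed by 2.55 (adjusted p = 0.0513, not called). With the gender label in the model 11 of these genes were not called, namely Hhip (1.82, adjusted p = 0.0967), Gfap (1.27, 0.125), Mtx2 (0.0602), Zdbf2 (0.159), Aldoc (0.158), Scd1 (0.0714), H2-Aa (0.0774), Uba1y (0.189), Tbx15 (0.167), Wfdc17 (0.0665) and Pcdhb2 (0.109). With the Y-linked level these genes except Hhip were not called either, nor was BC040756 (-2.39, 0.0654), at up to 0.176 for Pcdhb2.

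Between the models the FGF and EGF (0.42, 1.01e-05), Notch (0.46, 8.65e-05) and neural stem cell lists (0.48, 0.000593) also differed, each with an adjusted p of 0.228 with an estimated correlation, led by Fgfr2 at 2.02, Fgfr3 at 1.66 and Jag1 at 1.61. Oligodendrocyte progenitors (0.60, 0.00188), Purkinje cells (1.04, 0.00188), choroid plexus (0.97, 0.0324) and the Shh pathway (0.30, 0.0324) were positive. MHC class II (-1.05, 0.00227), lymphocytes (-0.20, 0.00266, with scores that cannot be separated from background), interferon (-0.36, 0.00975), p53 targets (-0.62, 0.0113) and hypoxia (-0.33, 0.0331) were negative. With an estimated correlation the adjusted p was 0.596 for choroid plexus, Shh and interferon and 0.505 for the others. With the gender label in the model 6 of these lists lost their calls, oligodendrocyte progenitors at -0.10 (adjusted p = 0.719), Shh at 0.06 (0.719), stem cells at 0.27 (0.0519), choroid plexus at 0.58 (0.213), interferon at -0.20 (0.136) and hypoxia at -0.30 (0.389). The Shh call ended without GFD-Ptch replicate 2 (0.195), NG-Ptch replicate 4 (0.13, 0.101), NG-Smo replicate 1 (0.117) or 2 (0.0575) or GFD-Smo replicate 4 (0.0671). Choroid plexus lost its call without GFD-Smo replicate 2 (0.40, 0.227), NG-Ptch replicate 4 (0.42, 0.128), GFD-Ptch replicate 1 (0.0877) or NG-Smo replicate 2 (0.0575) or 3 (0.0630). The p53 call ended without GFD-Ptch replicate 1 (-0.31, 0.260) or NG-Smo replicate 3 (0.0511). The hypoxia call ended without GFD-Ptch replicate 2 (-0.18, 0.182), NG-Smo replicate 1 (0.0841) or 2 (0.0575), GFD-Smo replicate 4 (0.0606) or NG-Ptch replicate 4 (0.0524).

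By this test 479 genes had a positive and 280 a negative difference between the models, with 235 and 53 of at least 2-fold. The count of 759 was 457, 424 and 503 without NG-Ptch replicates 1, 2 and 5, and 394 and 248 without GFD-Ptch replicates 1 and 2. It was 1285 without the transplanted tumour, and 457, 444 and 447 without GFD-Smo replicates 1, 2 and 3. Without GFD-Ptch replicate 2 Mtx2 (adjusted p = 0.131), Scd1 (0.0611), Hhip (0.0679) and Gfap (0.164) missed the threshold, and without GFD-Ptch replicate 1 H2-Aa (0.0704). Without either of them Zdbf2, Aldoc, Tbx15, Wfdc17 and Pcdhb2 missed it at 0.0629 or more, and Uba1y did without replicate 1 (-1.26, 0.122). Leaving out any other array also ended the calls of Zdbf2, Uba1y, Tbx15 and Pcdhb2, at 0.0501 or more, with these exceptions. Zdbf2 kept its call without NG-Ptch replicate 4, NG-Smo replicate 3 or any GFI-Ptch array, and Uba1y without GFI-Ptch replicate 3 or 4 or GFD-Ptch replicate 2. Tbx15 kept it without NG-Ptch replicate 4, NG-Smo replicate 4 or GFI-Ptch replicate 1, 2 or 4, and Pcdhb2 without NG-Smo replicate 2 or GFI-Ptch replicate 2, 3 or 4. Aldoc missed it also without NG-Ptch replicate 1, 2 or 4, NG-Smo replicate 4 or GFD-Smo replicate 1, 2 or 3 (0.0533 or more). Wfdc17 missed it also without NG-Ptch replicate 1, 4 or 5 or GFD-Smo replicate 2 or 3 (0.0504 or more). Sox2 was called without any 1 GFI-Ptch array or NG-Smo replicate 2 (0.0176 to 0.0485), and Gli1 (0.64) without the transplanted tumour (0.0182).

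Across genes, the changes of GFD minus NG in Ptch and in Smo tumours ran against each other, with a Pearson correlation of -0.245 and a Spearman correlation of -0.170, where genes are not independent replicates. Of the 1058 genes called in Smo tumours 397 (37.5%) had the same sign in Ptch tumours, where 42.3% of all genes did. Vopp1 was called in both, and rose in GFD-Ptch and fell by 0.26 in GFD-Smo. For GFI minus NG in Ptch tumours the correlations with the Smo contrast were -0.143 and -0.0956, and 447 of the 1058 genes (42.2%) had the same sign, against 44.9% of all genes.

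The mitosis, PI3K and IGF, Wnt and Polycomb lists were called in no contrast. Mitosis stood at -0.04 in Ptch (adjusted p = 0.207) and -0.06 in Smo tumours (0.25) for GFD minus NG, PI3K and IGF at 0.00 (0.207) and -0.09 (0.25), Wnt at -0.03 (0.742) and -0.11 (0.83), and Polycomb at -0.03 (0.343) and -0.14 (0.513). Within the Wnt list Wnt5a rose by 1.07 in GFD-Smo, and the inhibitor Wif1 was higher by 1.40 in NG-Smo than in NG-Ptch. For every called list the median, the mean and the test had the same sign. The filter on dim genes also ended the calls of the mesenchymal list in GFD minus NG in Ptch tumours (0.751) and in the average (0.349), of the Shh pathway (0.248) and progenitors (0.148) in GFI minus NG, and of choroid plexus in Smo tumours (0.145) and in the difference (0.254). It ended those of FGF and EGF in GFI minus GFD (0.0810), S phase in the average (0.0662) and the Shh pathway in the difference (0.314) as well. Quantile normalization also ended those of the Shh pathway in GFI minus NG (-0.12, 0.0910) and in the difference (0.28, 0.0651) and of choroid plexus in Smo tumours (0.45, 0.0591). With array weights choroid plexus stood at 0.30 (0.177) in Smo tumours and 0.61 (0.137) in the difference, and the lymphocyte list at -0.04 (0.177) in Smo tumours. In GFI minus NG the Shh pathway (-0.01, 0.583), progenitors (-0.03, 0.107), stem cells (-0.11, 0.107) and fibroblasts (0.24, 0.113) were not called with weights, nor was the mesenchymal list in GFD minus NG in Ptch tumours (-0.19).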

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

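Every test in this part was chosen only after the result was seen, except the test of a mislabelled NG-Ptch replicate 4, which was set before, and the contrast between the models, which was planned.

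Prm1 was high in all GFD-Smo arrays (11.59 to 11.79) and in 9 Ptch arrays (10.69 to 11.54), low in all NG-Smo arrays (7.1 to 7.6) and at 8.8 in NG-Ptch replicate 4, which lay apart from its nearest replicate at 11.2. Spermatid expression was excluded, since 8 other spermatid genes differed between GFD-Smo and NG-Smo by a median of -0.0153 (range -0.05 to 0.05). A mislabelled NG-Smo tumour was excluded for NG-Ptch replicate 4, as it lay closer to NG-Smo in 12 of the 86 genes that separate the groups (14.0%, where under 50% excludes it). A draft had set this bound at 10%, which would have left the mislabelling open. The bound was widened before the result was seen but when the array was known to correlate with its replicates. Ptch1 read 12.14 in NG-Ptch replicate 4, against 10.62 to 11.78 in the other 9 Ptch arrays and 12.25 to 12.75 in NG-Smo. The test covered an NG-Smo tumour only, so another genotype or another mislabelling of this array was not tested and stays open. Sequence of an engineered allele that Prm1 probes detect may be the source, as the Prm1 polyadenylation sequence is used in some transgene constructs, and stays open because the lowest Ptch level (8.8) lay above the highest NG-Smo level and no construct sequence was at hand.

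The transplanted tumour, GFI-Ptch replicate 4, had higher levels of muscle genes than the mean of the other 3 GFI-Ptch arrays, by 4.78 for Myh3, 4.51 for Actc1 and 3.88 for Des. Adult skeletal muscle of the host was excluded as the source, because 12 genes of adult fibres exceeded the other arrays by a median of 0.57 and 13 genes of developing muscle by 2.80, a difference of -2.23. The ranges were -0.34 to 2.74 (Ckm at 0.65 and Myh4 at -0.32) and -0.31 to 4.78, with 5 and 12 genes over 1 log2 unit. Muscle differentiation within the tumour may account for the 2.80, and stays open since 1 array cannot tell it from another tissue or tumour in the sample. Some of these genes were also high on average in GFD-Smo. Actc1 read 10.57, Myl4 9.53 and Myod1 9.99 there, against 8.21, 8.24 and 8.43 in the other GFI-Ptch arrays. The other developing muscle genes differed less, and Myf5 and Chrng were lower in GFD-Smo.

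Astrocyte genes were lower in GFD than in NG tumours of Ptch mice and higher in those of Smo mice, and the list's difference between the models was 2.07, with adjusted p = 0.352, 0.162 and 0.228 with an estimated correlation and 0 of 14 members called over all genes by limma in Ptch tumours (3375 genes with an unadjusted p under 0.05). The values argue against a larger share of all normal brain cells alike in GFD-Smo tumours as the only difference. The microglia and macrophage list (18 genes) stood at -0.33 (quartiles -0.59 and -0.06), with scores of 9.14 to 9.32 against 9.53 to 9.72 in NG-Smo. The endothelium list stood at 0.39 (quartiles 0.15 and 0.54). These quartiles are over genes that can vary together, not over tumours. The mean microglia score was 9.22 in GFD-Smo and 9.21 in NG-Ptch. Such a share beside a high myeloid level in NG-Smo is therefore not excluded. As the fibroblast list (0.46) was higher like endothelium, and the Purkinje score in GFD-Smo replicates 1 to 3 (9.19 to 9.51, against 7.84 in replicate 4), more of some normal cell types may contribute, which was not tested and stays open. Sex may contribute in Ptch tumours and stays open, because both GFD-Ptch arrays and no NG-Ptch array had Y-linked transcripts. With the Y-linked level in the model the astrocyte list (14 genes) stood at -0.63 (quartiles -0.96 and -0.36), little changed from a median of -0.67 without it. With the gender label it stood at -0.27. That label was ND in 3 of the 4 NG-Ptch arrays and went against the Y-linked genes in 3 arrays, so the -0.27 is a poor guide to sex. Subtype or cell of origin may account for the 2.07 and cannot be told apart from the Cre driver in Smo tumours or from the sex of the tumours in the GFD-Ptch and NG-Ptch arrays.

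Of 336 groups of arrays tested for 1 array far from its replicates (58 genes and 26 list scores in 4 groups), 24 passed, where chance gives about 1 in 20 groups, or 17. NG-Ptch replicate 4 lay apart in Ifi203 (9.63, nearest replicate 10.6) and in the choroid plexus score (9.17, nearest 7.43). The transplanted tumour lay apart in Terc (10.34, nearest 8.07), Wfdc17 (9.32, nearest 11.07) and Lyz2 (10.73, nearest 11.68). GFI-Ptch replicate 2 did so in BC040756 (7.44, nearest 6.45) and GFI-Ptch replicate 1 in the MHC class II score (8.85, nearest 7.95). Among NG-Smo arrays, replicate 3 did so in Gpr50 (9.68, nearest 7.06) and Gpnmb (10.11, nearest 11.13), and replicate 2 in Grb10 (9.03, nearest 7.01) and the granule neuron progenitor score (11.15, nearest 11.26). NG-Smo replicate 1 did so in Minar1 (10.16, nearest 9.11), Cybb (10.6, nearest 10.36), Clec7a (9.14, nearest 8.39) and the Purkinje score (8.78, nearest 7.97). Among GFD-Smo arrays, replicate 4 did so in Rgs13 (8.01, nearest 8.84), Scd1 (11.37, nearest 11.03), Atoh1 (12.14, nearest 11.83) and the differentiated neuron score (9.21, nearest 9.92). GFD-Smo replicate 3 did so in Tecta (7.18) and the PI3K and IGF score (9.99, nearest 10.12), and replicate 2 in Aqp4 (12.19, nearest 12.35) and the choroid plexus score (9.68, nearest 7.68).

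The test of the difference between the models was passed by 759 genes, among them Mtx2 (4.89), Zdbf2 (4.51), Aldoc (4.39), Scd1 (3.90), Prm1 (3.78), Aqp4 (3.72), Hhip (2.33), Gfap (1.88), and by H2-Aa (-3.32), the Y-linked Uba1y (-2.98), Tbx15 (-2.97), BC040756 (-2.84), Wfdc17 (-2.76) and Pcdhb2 (-2.40). Lists that differed were Purkinje cells (1.04), choroid plexus (0.97), oligodendrocyte progenitors (0.60), neural stem cells (0.48), Notch (0.46), FGF and EGF (0.42), the Shh pathway (0.30), lymphocytes (-0.20), hypoxia (-0.33), interferon (-0.36), p53 targets (-0.62) and MHC class II (-1.05). None of them passed with an estimated correlation (adjusted p = 0.228 to 0.596), and with the gender label oligodendrocyte progenitors stood at -0.10 (0.719), Shh at 0.06 (0.719) and choroid plexus at 0.58 (0.213).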

How the results depend on the processing

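The fits with the level of Y-linked genes and without the transplanted tumour and NG-Ptch replicate 4 together were chosen only after the results were seen, and the rest were planned. Values are numbers of called genes unless stated, with the reported count in brackets, and the cause was not tested for any change. Leaving out 1 of the 2 GFD-Ptch arrays left a lone array, assumed to vary like the other groups. GFD minus NG in Ptch tumours (2) gave 4 with quantile normalization, 4 with median centring, 245 with the compared groups only, 8 with a trended and robust prior and 565 with array weights. It gave 0 in limma with the gender label and 0 with a replicate block (2962 and 3116 genes with an unadjusted p under 0.05), 1 with the Y-linked level and 103 without both arrays. GFI minus NG in Ptch tumours (0) gave 12 with centring, 4 with the filter on dim genes, 1 with the compared groups only, 180 with weights, 2 with the gender label and 2 without both arrays. GFI minus GFD (1) gave 2 with quantile normalization, 2 with the trended prior, 26 with weights and 50 without both arrays. It gave 0 in limma with the compared groups only, the gender label, the block or the Y-linked level (unadjusted 1125, 2427, 1803 and 2151). GFD minus NG in Smo tumours (1058) gave 1740 with weights. Smo minus Ptch in NG tumours (208) gave 42 with the compared groups only, 419 with weights, 96 with the gender label and 34 with the block. In GFD tumours (3110) it gave 6709 with the compared groups only and 5906 with weights. The average over models (178) gave 400 with the compared groups only, 747 with weights, 80 with the gender label, 101 with the Y-linked level and 372 without both arrays. The difference between models (759) gave 1293, 1484, 188, 149 and 1212 in the same order, and 417 with the block. Without each array in turn the counts ran from 1 to 144, 0 to 8, 1 to 47, 643 to 1553, 75 to 384, 997 to 4376, 13 to 358 and 248 to 1285 in the order of the 8 contrasts. Called lists fell to 0 in each contrast with an estimated correlation. With fry they fell to 0, 0 and 0 in the Ptch contrasts (of 10, 7 and 7) and to 11 of 14 for GFD minus NG in Smo tumours. They fell to 1 of 8 for Smo minus Ptch in NG and 8 of 13 in GFD tumours, 3 of 11 in the average and 7 of 13 in the difference. They were 5, 8 and 8 with the gender label in GFD minus NG in Ptch tumours, Smo minus Ptch in GFD tumours and the difference, and 4 with the Y-linked level in the first. They were 3 for GFI minus NG and 11 for GFI minus GFD both with weights and without both arrays. Without each array in turn they ran from 8 to 13, 3 to 10, 6 to 11, 12 to 14, 4 to 10, 11 to 15, 8 to 16 and 10 to 14. The correlations across genes with the Smo contrast ran from -0.286 to -0.169 and from -0.166 to -0.0623. The Shh pathway list in GFI minus NG in Ptch tumours turned to 0.01 with the gender label and to 0.06 without both arrays. With the gender label stem cells in GFD minus NG in Ptch tumours turned to 0.05 and oligodendrocyte progenitors in the difference to -0.10, and choroid plexus in GFD minus NG in Smo tumours ran from -0.01 without GFD-Smo replicate 2 to 0.62 without replicate 3. List calls ended in 26 cases with the gender label, 14 with the Y-linked level, 12 with the filter on dim genes, 9 with weights, 7 each with quantile normalization, the block and both arrays left out, 2 each with centring and the compared groups only, and 1 with the trended prior. For the 83 list calls, each a list in 1 contrast, 2236 of 2403 alternative values kept sign and call, 162 lost the call and 5 changed sign. These list tallies cover refits with camera at the preset correlation only. They leave out fry and the estimated correlation, under which every list call was lost. Fits without an array outside a contrast cannot turn a value. For 156 pairs of a named gene and a contrast, 262 of 4523 alternative values lost the call and 37 gained it. The other 4224 include many pairs with no call to lose, counted as unchanged if they stayed uncalled, whatever their sign. Replicate numbers did not pair the arrays across groups, as 29 pairs of the same number correlated at a mean of -0.0345 (-0.310 to 0.187), and 2 of 17 arrays were closest to their own number, so the block describes no design. No signal over background was used here, so genes at low values cannot be separated from background.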

Other observations

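The tests in this part, the counts over other splits of the arrays included, were chosen only after the results were seen, as were the genes named. In GFD-Smo tumours (n = 4) the RNA-binding protein gene Igf2bp3, which like Igf2bp1 is mainly expressed in the embryo, was at 8.22 ± 0.18 where NG-Smo (n = 4) had 6.31 ± 0.04, a change of 1.91 (SE 0.070, adjusted p = 3.26e-10, limma). Igf2bp1 was at 8.14 ± 0.16 against 6.82 ± 0.12. In the Ptch groups Igf2bp3 read 6.35 to 6.40. Of 19 measured imprinted genes, in a list that held genes picked after their values were seen, 3 were called in that contrast (Grb10, Zdbf2 and Ndn, two-sided Fisher p = 0.0766), so imprinted genes as a set are not shown to differ.

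Protocadherin beta genes, which encode neuronal adhesion proteins from 1 gene cluster, were lower in GFD-Smo than in NG-Smo in 10 of 22 measured members and higher in 0 on the deposited scale (limma), in 10 and 0 with quantile normalization and in 8 and 0 with median centring. The medians were -0.70, -0.69 and -0.70, and 19 of 22 lay below 0 on the deposited scale. Pcdhb3 was at 7.51 ± 0.12 in GFD-Smo and 8.83 ± 0.27 in NG-Smo, and Pcdhb2 at 7.38 ± 0.05 and 9.20 ± 0.56. In NG-Smo against NG-Ptch 3 members were higher and 0 lower, on each of the 3 scales. In GFD-Smo against GFD-Ptch 0 were higher and 3, 2 and 1 lower on the 3 scales, with 19 of 22 below 0 and a median of -0.41 on the deposited scale. The probe sets of such paralogs can share sequence, which was not tested.

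Foxr2 was at 6.14 to 6.32 on average in NG-Ptch, GFD-Ptch and GFD-Smo, and its SD was 1.82 in GFI-Ptch (mean 7.19) and 2.83 in NG-Smo (mean 7.80). In GFI-Ptch the high level was that of the transplanted tumour, at 9.92, which lay 3.64 above the mean of the other arrays of its group. The GFD-Smo arrays were closer to each other than those of any other group, with a median SD per gene of 0.0735 against 0.0822 to 0.144.

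Other splits of the same arrays into groups of the same sizes were counted for the 4 contrasts whose fits allow it. For GFD minus NG in Smo tumours 1058 genes were called against at most 57 in the other splits (1 of 35 as large). Smo minus Ptch in NG tumours gave 208 against at most 3 (1 of 35). In both the real grouping gave far more genes than any other split. With 35 splits the share cannot fall below 1 in 35. Exchanging arrays also takes them as independent, which the labels do not show, so chance is not excluded. For the average over the models the count was 178 against at most 161 in the other splits drawn (1 of 100, drawn from 1050 possible splits). Splits that were not drawn may exceed 178. Labels were exchanged in both models at once, so a difference in Smo tumours alone could give this result. The splits therefore do not exclude chance for a difference shared by the models, and the count also fell without GFD-Ptch replicate 2. For GFI minus NG in Ptch tumours limma called 0 genes, with 1701 at an unadjusted p under 0.05. Any split gives at least 0 (35 of 35, the highest 4), so the splits decide nothing there.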
